A study of Mus musculus with 20 samples.

How the data were processed

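The series measured RNA in 20 mouse U14 tumour samples, prepared from total RNA with a stranded mRNA kit and sequenced on an Illumina NovaSeq, per the labels' protocols. Groups and replicate numbers were taken from the labels: Solution, Plerixafor, anti-PD-1 and Combination, with 5 libraries each, no library left out and no column of other samples. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the fragments of the library), 1 column per library and 18722 genes by symbol, none listed more than once and none at 0 in every library. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq 0.11.2, StringTie 2.1.4 and DESeq2 1.28.1 were used with the genome build GRCm39; no role or order was stated, and the tool that made the FPKM is not given in the sources used here. Whether HTSeq counted by strand is not stated either, so overlapping and antisense genes can share reads, as can near-identical copies. A gene name table of GRCm38 matched 17985 of the symbols and served for names only; no coordinates were used.

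Within a gene the FPKM values of all libraries were whole multiples of 1 step, to within 0.02 of a whole number, for 18722 of 18722 genes, which gave back the reads behind each value. The recovered totals ran from 16565807 to 19833872 reads per library. These reads carried no molecular identifiers and were used for depth and for 1 alternative fit. Among 40 pairs of libraries within groups the median chi-square per gene was 2.00 to 84.08, so no library was a copy of another in its group. Pairs across groups were not compared in this way.

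FPKM values were transformed as log2(FPKM + 1) and tested with limma 3.58.1 in R 4.3.3 (trended empirical Bayes), with all 20 libraries in 1 fit on group (16 residual degrees of freedom). Genes with an FPKM of at least 1 in at least 5 libraries, 12687 of them, were tested in 6 contrasts: each treatment against Solution, Combination against each single agent, and the interaction, which is the effect of anti-PD-1 with Plerixafor minus its effect without. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. The tests, groups, gene lists, naming rule and most alternatives were set before the data were examined. Count-based tests planned for recovered reads were not run, because the deposited unit is FPKM; limma-voom on these reads was added after the data were seen. The correlation of Cxcr4 with Tox was planned over all libraries and was computed within clusters because the libraries formed 2 of them.

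The 28 gene lists covered the CXCR4 axis, T cells, T cell exhaustion, cytotoxic effectors, naive and memory T cells, regulatory T cells, NK cells, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells, mast cells, interferon response, MHC class I and class II presentation, JAK-STAT signalling, chemokines, fibroblasts and matrix, endothelium, epithelium, proliferation, hypoxia and glycolysis, immediate early and heat shock genes, skeletal muscle, skin keratinocytes, adipocytes, erythroid cells and mitochondrially encoded genes. They held 402 different genes, 12 of them on more than 1 list, and none was chosen by the study from these libraries. Lists with at least 5 tested members, 26 in all, were tested with limma's camera at a preset correlation of 0.01; the keratinocyte list had 2 tested members, and no mitochondrially encoded gene was in the table. No list call held with an estimated correlation in any contrast, as its adjusted p-values show in the results. Limma's fry was run as an alternative, and tests whether a list's genes move on balance one way.

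Genes were named by a fixed rule: Cxcr4, Cxcl12, Pdcd1, Tox, Jak2 and Stat3 always; among genes past the threshold that are not Gm or Rik models and have a mean FPKM of at least 2 in the higher group, the 10 largest rises and the 10 largest falls; where fewer than 5 passed in a direction, the 5 with the smallest p in it; and of each list described, up to 4 members with the smallest p. Some list members were named beyond this rule after their values were seen: Tigit and Nr4a2 in the exhaustion list. Rhox5, Top2a, Col1a1, Lyz2, Cd3e and Acta1 in the marker plot were also chosen afterwards.

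Ratios of 8 genes to the mean of 5 T cell transcripts were compared by exact two-sided permutation of 5 against 5 libraries (252 assignments), adjusted over 40 tests. Correlations used 1e+05 permutations, the smallest p of which is 1e-05. Overlaps between contrasts with shared Solution libraries were set against 100 simulations of unchanged groups, independent lists, and 10 divisions of the controls. Each count of calls was recomputed for 100 splits of the libraries.

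Processing choices varied by plan were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, TPM, median-of-ratios scaling, quantile normalisation, a fit of only the groups compared, the replicate number as a block, array weights, an estimated correlation, fry, and leaving out each library in turn. Added after the data were seen were limma-voom, the muscle level as a covariate, anti-PD-1 library 4 alone in its group, leaving out the 3 libraries farthest from their groups, and a correlation with the T cell mean regressed out of both genes.

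The steps were tested on simulated data. For Plerixafor against Solution, with 12687 genes of which 200 were changed, over 10 runs, limma recovered 45.8% of 1.5-fold, 77.8% of 2-fold, 95.2% of 4-fold and 98.6% of 8-fold changes, at a false discovery share of 5.82%. Camera called a T cell list lowered by 1 log2 unit in 20 of 20 runs, with 2 calls of other lists. Each gene was drawn independently in these simulations, so they do not show how often camera calls lists falsely where genes move together. Reads were recovered with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.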

Results

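RNA sequencing gave 20 libraries from tumours of U14, a mouse cervical cancer cell line, in 4 groups of 5. The control group received the solution alone (Solution), and the others received Plerixafor, an antagonist of the chemokine receptor CXCR4, an antibody against the checkpoint receptor PD-1 (anti-PD-1), or both agents (Combination). The series concerns CXCR4, the transcription factor TOX in exhausted CD8 T cells, and JAK2 and STAT3. The table gave FPKM for 18722 genes, and 12687 genes with an FPKM of at least 1 in at least 5 libraries were tested. The depth recovered from the values was 18479251 to 19820124 reads per library in the Solution group, 17392027 to 18774688 in the Plerixafor group, 16565807 to 19833872 in the anti-PD-1 group and 17338691 to 19026511 in the Combination group. Group values are mean FPKM ± SD over n = 5 libraries, log2 fold changes carry their standard error (SE), and all tests were two-sided. The p-values measure the spread between these libraries, which may in part be technical, since the labels do not say whether each library came from a separate animal.

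The libraries fell into 2 separate clusters along the first principal component, which held 68.4% of the variance. The Plerixafor and Combination libraries scored 22.75 to 94.33 on it, and the Solution and anti-PD-1 libraries -78.6 to -43.51. The second component held 20.2% and set apart the anti-PD-1 libraries 1, 5 and 2, at 121.47, 44.44 and 41.71. Each group lay wholly in 1 cluster, and the labels name no batch.

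Plerixafor against Solution asks what the CXCR4 antagonist changed on its own. Proliferation genes were higher in the Plerixafor tumours, and genes of many host cell types were lower: T cells, macrophages, neutrophils, dendritic cells, mast cells, fibroblasts and endothelium. Other lists, such as NK cells, naive and memory T cells and erythroid cells, were not called. Rises and falls here are differences between the groups, and an effect of the drug was not told apart from tumours of different make-up. Cxcr4, its ligand Cxcl12, Pdcd1 and Tox were all lower. A set of genes nearly silent in the Solution tumours, led by the homeobox gene Rhox5, was high in every Plerixafor library.

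By limma, 9577 of the 12687 genes passed an adjusted p of 0.05, 5370 higher and 4207 lower in the Plerixafor tumours, and 4839 of them differed by more than 2-fold. The median log2 fold change of all tested genes was 0.13, and after median-of-ratios scaling it was -0.01, with 49.3% of calls higher in place of 56.1%.

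The genes named in the series fell or kept their level. Cxcr4 had 7.80 ± 4.52 FPKM under Plerixafor against 45.4 ± 12.02 in the controls, a log2 fold change of -2.47 (SE 0.46, adjusted p = 8.49e-05), and the highest Plerixafor library, at 15.5, lay below the lowest Solution library, at 23.9. Cxcl12 fell from 83.1 ± 31.0 to 17.7 ± 17.9 FPKM (log2 fold change -2.47, SE 0.51, adjusted p = 0.000243). Pdcd1, which encodes PD-1, fell from 14.1 ± 2.98 to 2.62 ± 1.32 FPKM (log2 fold change -2.11, SE 0.43, adjusted p = 0.000248). Tox fell from 2.70 ± 1.29 to 0.284 ± 0.127 FPKM (log2 fold change -1.47, SE 0.19, adjusted p = 1.16e-06). Jak2 fell by less, with a log2 fold change of -0.51 (SE 0.18, adjusted p = 0.0146), from 13.6 ± 2.25 to 9.31 ± 2.02 FPKM. Stat3 had 51.8 ± 9.80 against 61.7 ± 4.90 FPKM and did not pass (log2 fold change -0.26, SE 0.19, adjusted p = 0.217), although it passed after median-of-ratios scaling (-0.42), after quantile normalisation (-0.44) and with array weights (-0.38).

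**Figure D1:**
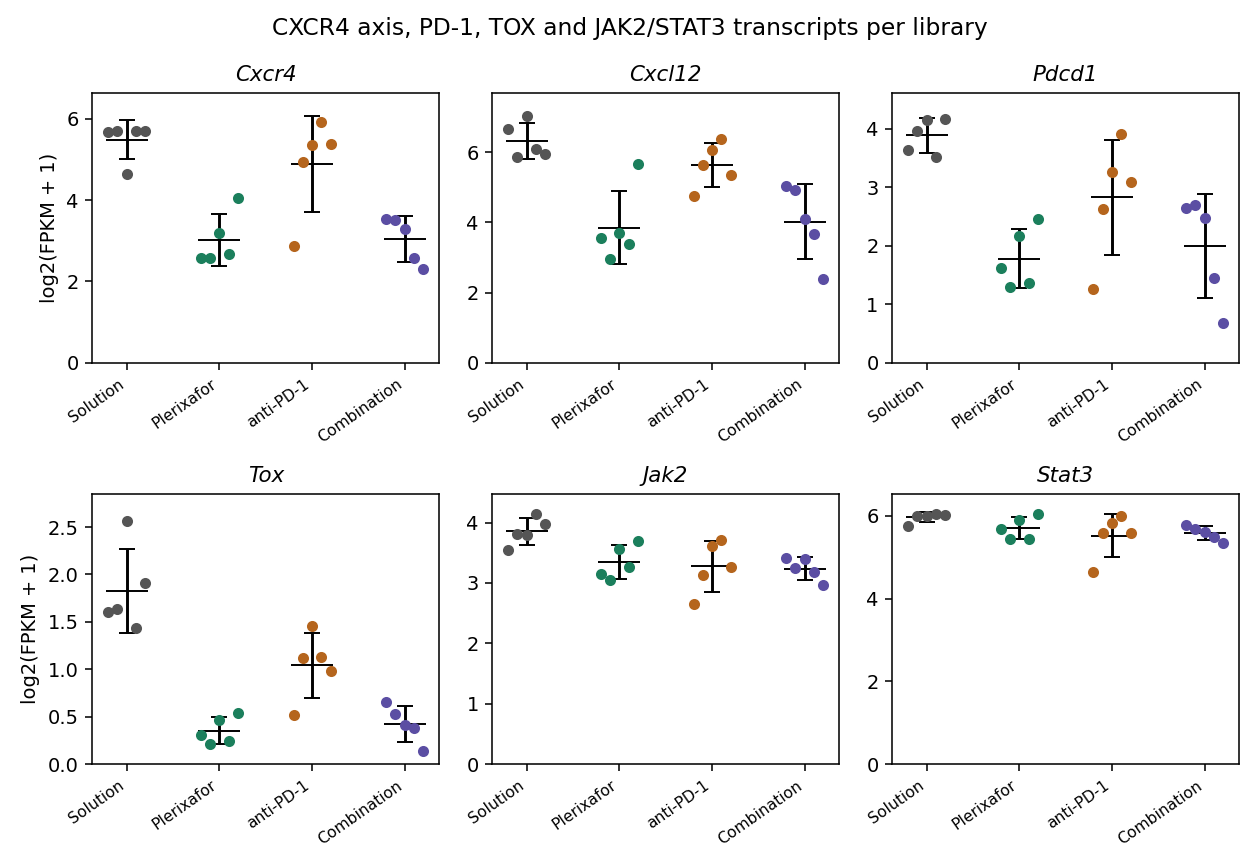
Expression, as log2(FPKM + 1), of Cxcr4, Cxcl12, Pdcd1, Tox, Jak2 and Stat3, with 1 point per library and bars at the mean ± SD of each group of 5. Mean Cxcr4 was 45.4 FPKM in the Solution group, 7.80 under Plerixafor, 35.1 under anti-PD-1 and 7.77 in the Combination group.

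Rhox5 rose most, from 0.765 ± 0.561 to 470 ± 100 FPKM (log2 fold change 8.09, SE 0.51, adjusted p = 1.49e-10), and the lowest Plerixafor library had 301.7. Bmp4 (6.18), Gchfr (5.89), Pitx1 (5.80), Dcaf8l (5.66), the glucose transporter gene Slc2a3 (5.46) and Tex11 (5.33) followed on the log2 scale. Prl2c2 (6.01), Prl2c3 (5.55) and Prl2c5 (5.22) also rose, and as near-identical copies they can share reads, so their separate levels are uncertain. The largest falls were in Retnla (-5.18), Ear2 (-4.97), Atp6v0d2 (-4.63), Chil3 (-4.56), Clec3b (-4.55), Cd5l (-4.38), Ptn (-4.24), Ctsk (-4.21) and Col6a5 (-4.16). Apoe fell from 6762 ± 893 to 430 ± 395 FPKM (log2 fold change -4.31, SE 0.60, adjusted p = 3.42e-06).

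T cell genes fell together, all 16 tested members of the list both over all genes and adjusted over the list alone, with a median log2 fold change of -2.07. Camera called the list lower at an adjusted p of 0.000158, and adjusted p = 0.544 with an estimated correlation, a value shared by all 17 lists called in this comparison. Cd8a fell from 23.5 ± 6.67 to 4.28 ± 2.78 FPKM, and Cd247 (-1.37), Cd28 (-1.80) and Zap70 (-2.07) fell on the log2 scale. The exhaustion list was called lower at a median of -1.40 (adjusted p = 0.0211), yet it moved both ways: 12 of 17 genes fell (13 adjusted over the list alone), Id2 by 2.78 on the log2 scale, while Eomes (2.77), Tigit (1.19) and Nr4a2 (0.66) rose. Eomes reached 35.4 ± 9.96 FPKM against 4.37 ± 2.01 in the controls, while T cell genes fell, and whether T cells carried this RNA was not tested. Cytotoxic effector genes were called lower at a median of -1.40 (adjusted p = 0.0117), with 12 of 15 falling on both counts, among them Gzmk (-1.61), Tbx21 (-1.64) and Nkg7 (-2.47). The regulatory T cell list (median -1.13, adjusted p = 0.0155, 7 of 8 lower) and the B and plasma cell list (-1.61, adjusted p = 0.0382, 7 of 7 lower) were also called, with equal counts over the lists alone. The B and plasma cell call was lost without Solution library 1 (adjusted p = 0.061) or 3 (0.0546). Camera did not call naive and memory T cell genes (median -0.91, adjusted p = 0.0613) or NK cell genes (-1.12, adjusted p = 0.0613). In each list 7 of 10 genes were lower and 1 higher, Id3 (2.07) and Klra4 (2.73), and NK cell genes were called without Plerixafor library 5 (adjusted p = 0.0407).

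Most myeloid and antigen presentation genes fell too. All calls here had an adjusted p = 0.544 with an estimated correlation. Macrophage and monocyte genes had a median of -2.12 (adjusted p = 0.00036, 17 of 18 lower), among them Mrc1 (-2.57), Cd68 (-2.69) and Trem2 (-3.58). Neutrophil genes had a median of -2.41 (adjusted p = 0.0108, 9 of 12 lower), led by Csf3r (-2.29) and Mmp9 (-3.90). Dendritic cell genes (median -1.22, adjusted p = 0.0117, 9 of 11 lower) and mast cell genes (-1.95, adjusted p = 0.0199, 7 of 7 lower) were called as well. MHC class I genes (-1.83, adjusted p = 0.0116, 10 of 14 lower) included H2-D1 (-2.50) and H2-K1 (-2.20), which are similar enough to share reads. MHC class II genes fell without exception, 11 of 11 (median -1.94, adjusted p = 0.00444), with Ctss at -3.10 and H2-Aa at -2.36. For these 6 lists the counts adjusted over the list alone equalled those over all genes. Chemokine genes were lower at a median of -1.67 (adjusted p = 0.0155, 13 of 22 lower, 11 adjusted over the list alone), with Ccl11 (-3.39) and Ccl8 (-3.16) falling and Cx3cl1 (2.78) rising. JAK-STAT genes were called lower (median -0.85, adjusted p = 0.0021, 15 of 25 lower on both counts), with Jak1 (-1.40), Stat5a (-1.69) and Stat5b (-1.96) falling and Lif (1.40) rising.

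Stromal genes fell and cycling genes rose, each called list again with an adjusted p = 0.544 with an estimated correlation. All 18 fibroblast and matrix genes fell (median -2.55, adjusted p = 2.11e-06), Pdgfra by 2.52, Pdgfrb by 2.37 and Mmp2 by 3.79 on the log2 scale, and Col6a1 fell from 433 ± 68.5 to 44.5 ± 37.3 FPKM. Endothelial genes fell by less (median -0.90, adjusted p = 0.00334, 11 of 13 lower, 12 adjusted over the list alone), with Pecam1 at -1.22 and Tek at -1.62. Adipocyte genes were called lower (median -2.04, adjusted p = 0.0211, 5 of 10 lower, 2 adjusted over the list alone). Of the proliferation genes 24 of 24 rose on both counts (median 3.05, adjusted p = 3.44e-07): Aurka went from 2.51 ± 0.491 to 35.5 ± 8.42 FPKM, and Mcm7 (2.74), Tpx2 (3.64) and Bub1 (3.79) rose too.

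Epithelial genes split, and the list was not called (median -1.98, adjusted p = 0.0938): the simple keratins Krt18 (3.27) and Krt8 (2.87) and Perp (2.74) rose, while 9 of 13 fell, such as the basal keratin Krt5 (-3.72). Part of the control level came with skin genes, since the skin keratinocyte list averaged 3.07 and 3.27 on the log2 scale in the Solution libraries 3 and 5 and at most 0.29 in the other Solution libraries; only 2 of its genes were tested, too few for the list test, and both fell. Camera did not call the CXCR4 axis list (median -1.48, adjusted p = 0.233): Mif rose from 294 ± 61.1 to 749 ± 119 FPKM, and 3 of its 5 genes fell, with Dpp4 at -1.48. Interferon response genes (median -0.27, adjusted p = 0.205, 3 of 24 lower, 0 adjusted over the list alone), erythroid genes (-0.75, adjusted p = 0.397) and skeletal muscle genes (1.36, adjusted p = 0.926) were not called. Their medians moved with single libraries: interferon was at -0.11, -0.42, -0.09 and -0.47 without Plerixafor library 2, 3, 4 or 5, erythroid at -0.39 without Solution library 5 and muscle at 0.65 without Solution library 2. Hypoxia and glycolysis genes went both ways, 4 higher and 4 lower, with Ndrg1 (1.93) and Vegfa (1.55) rising and Egln3 (-2.31) falling. Immediate early and heat shock genes also split, 6 higher and 5 lower. For these last lists, neither called, the median and mean lay above 0 (medians 0.09 and 0.21) while camera ranked the genes below the rest (adjusted p = 0.747 and 0.736). The hypoxia median was 0.15, 0.04 and 0.16 without Solution library 2 or 3 or Plerixafor library 4, and the immediate early median 0.12 without Solution library 1.

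**Figure D2:**
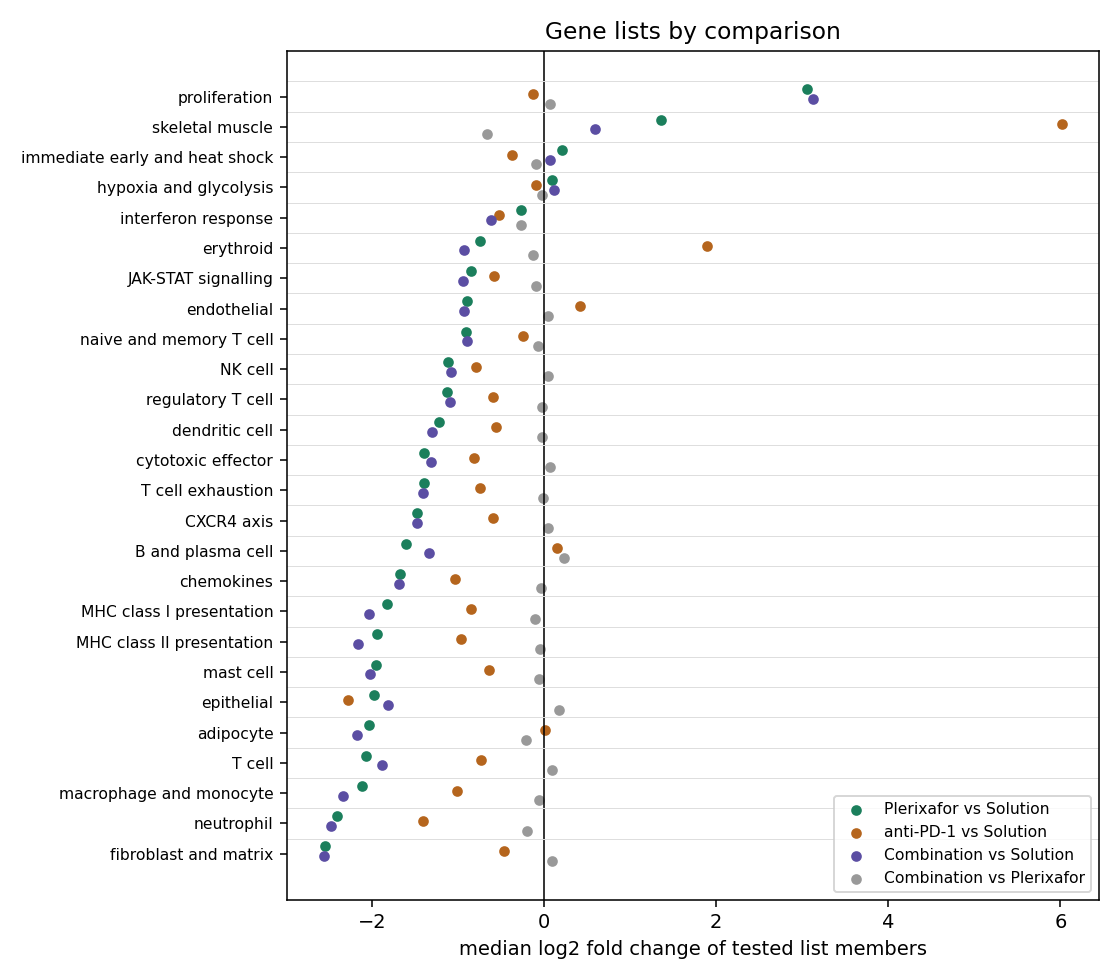
Median log2 fold change of each of the 26 tested gene lists for Plerixafor, anti-PD-1 and Combination against Solution and for Combination against Plerixafor. The proliferation list stood at 3.05 for Plerixafor and 3.12 for Combination against Solution, and the skeletal muscle list at 6.02 for anti-PD-1 against Solution.

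Anti-PD-1 against Solution asks what the checkpoint antibody changed on its own. Skeletal muscle genes rose by far the most, epithelial genes fell, and immune lists were called lower, though not with an estimated correlation (adjusted p = 0.684) and in part through 1 low library, anti-PD-1 library 1: without it the T cell median, for one, moved from -0.73 to -0.43. Tox fell, while Cxcr4, Cxcl12, Pdcd1 and Stat3 did not pass the threshold. Muscle RNA was uneven between the libraries: the muscle list held 23.45, 6.89, 2.90 and 8.05% of all FPKM in the anti-PD-1 libraries 1, 2, 3 and 5, 0.0428% in library 4, and at most 0.377% in any library of the other groups.

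By limma 1454 genes passed, 1063 higher and 391 lower, and 616 of them differed by more than 2-fold. The median log2 fold change of all genes was -0.11. After median-of-ratios scaling 62.8% of 1297 calls were higher in place of 73.1%, and after quantile normalisation 48.8% of 2240. The count rested on single libraries: it was 2 without anti-PD-1 library 5, 544 without library 2, 2427 without library 3 and 4112 without library 4. Leaving out Solution library 2, 3, 4 or 5 gave 779, 789, 779 and 582. No gene passed in a fit of these groups alone (2585 at an unadjusted limma p under 0.05) or with the muscle level as a covariate (780), against 767 by limma-voom and 4163 with array weights.

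Ckm rose from 54.5 ± 87.7 to 4511 ± 5308 FPKM (log2 fold change 6.66, SE 1.68, adjusted p = 0.0214), and Atp2a1 (6.62), Acta1 (6.59), Tnnc2 (6.37), Tnnt3 (6.27), Myh4 (6.16), Pvalb (6.11), Mb (6.07), Mylpf (6.02) and Tnni2 (5.93) rose with it. The largest falls were in Chil3 (-4.53), the keratins Krt19 (-4.21), Krt5 (-3.43) and Krt7 (-2.89), Ccl24 (-2.94), Rnase2a (-2.94), Wfdc18 (-2.78), Fxyd3 (-2.69), Fam25c (-2.66) and Csn3 (-2.58). Tox fell from 2.70 ± 1.29 to 1.10 ± 0.469 FPKM (log2 fold change -0.79, SE 0.19, adjusted p = 0.0175), and without anti-PD-1 library 5 it no longer passed (-0.77, adjusted p = 0.0523). Jak2 was lower at 9.003 ± 2.71 against 13.6 ± 2.25 FPKM (log2 fold change -0.58, SE 0.18, adjusted p = 0.0426). Its call was lost without Solution library 2, 3, 4 or 5 or anti-PD-1 library 1, 2 or 5, where the log2 fold change ranged from -0.59 to -0.42, and after TPM scaling (-0.58). Cxcr4 had 35.1 ± 19.4 FPKM (log2 fold change -0.59, SE 0.46, adjusted p = 0.341), Cxcl12 52.4 ± 21.8 (-0.69, SE 0.51, adjusted p = 0.323) and Stat3 47.2 ± 14.6 (-0.44, SE 0.19, adjusted p = 0.118), and Stat3 passed without anti-PD-1 library 4 (-0.56, adjusted p = 0.0348). Pdcd1, at 7.34 ± 4.64 FPKM, did not pass (log2 fold change -1.06, SE 0.43, adjusted p = 0.104) unless anti-PD-1 library 4 was left out (-1.33, adjusted p = 0.0285), or quantile normalisation (-1.09) or array weights (-0.92) were used.

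Camera called 16 lists, each with an adjusted p = 0.684 with an estimated correlation, and fry called only the epithelial and skeletal muscle lists. Muscle genes were higher, 15 of 15 on both counts (median 6.02, adjusted p = 9.96e-13). Epithelial genes were lower (median -2.28, adjusted p = 1.44e-05, 9 of 13 lower, 12 adjusted over the list alone), with Cdh1 (-2.28), Cldn4 (-2.57) and Krt17 (-1.86), where the Solution libraries 3 and 5 carried the skin genes described and anti-PD-1 library 3 kept an epithelial level of 3.41 against at most 1.47 in the other 4. Endothelial genes were higher at a small median of 0.42 (adjusted p = 0.00332, 3 of 13 higher, 4 adjusted over the list alone), with Kdr (0.63), Cdh5 (0.68) and Tie1 (0.73). Erythroid genes were called higher (1.89, adjusted p = 0.00592) with 0 of 5 genes past over all genes and 5 adjusted over the list alone (median 1.25 without anti-PD-1 library 1). Macrophage and monocyte genes were called lower (median -1.01, adjusted p = 0.00337), with Ccr2 (-0.92) and Mrc1 (-1.22) past the threshold and 4 of 18 lower adjusted over the list alone. Their median was -0.48 without anti-PD-1 library 1 (adjusted p = 0.00649), whose mean level was 4.96 on the log2 scale against 7.16 to 7.89 in the other 4. For dendritic cell genes (-0.56, adjusted p = 0.023) these were Batf3 (-1.34) and Itgax (-2.02), the same number over the list alone. NK cell genes (-0.79, adjusted p = 0.0173) had Klrb1c (-1.08) past over all genes and 5 of 10 over the list alone.

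The T cell (median -0.73, adjusted p = 0.0256), cytotoxic effector (-0.82, adjusted p = 0.0264), regulatory T cell (-0.59, adjusted p = 0.0468), neutrophil (-1.41, adjusted p = 0.024) and MHC class I (-0.85, adjusted p = 0.023) lists were called lower with 0 genes past on either count. The exhaustion list (-0.75, adjusted p = 0.0264) had Tox and Cd244a (-0.75) lower and Nr4a1 (1.41) higher, with 5 lower adjusted over the list alone. MHC class II genes (-0.97, adjusted p = 0.0264), chemokines (-1.04, adjusted p = 0.0264) and JAK-STAT genes (-0.58, adjusted p = 0.00332) were also called lower, each with an adjusted p = 0.684 with an estimated correlation. Single members passed in the first 2 of these, Ifi30 (-1.38) and Ccl17 (-1.24), on both counts, and Jak2 and Pim1 (-0.88) passed in the JAK-STAT list, with 0 adjusted over the list alone. Anti-PD-1 library 1, the lowest of its group in T cell and MHC class I genes, carried part of these falls. Without it the medians were -0.43 for T cells, -0.46 for cytotoxic effectors, -0.34 for regulatory T cells, -0.74 for neutrophils, -0.43 for MHC class I, -0.47 for exhaustion, -0.61 for MHC class II, -0.40 for chemokines and -0.37 for JAK-STAT genes. Calls were also lost without single libraries, with adjusted p in parentheses. Exhaustion was not called without anti-PD-1 2 (0.0608) or 3 (0.0627), cytotoxic effectors without anti-PD-1 1 (0.0672), 2 (0.0665) or 3 (0.0567), regulatory T cells without Solution 2 (0.0606) or 5 (0.08) or anti-PD-1 1 (0.0624), 2 (0.0787), 3 (0.0811) or 5 (0.0736), neutrophils without anti-PD-1 3 (0.0736), MHC class II without Solution 3 (0.0585) or anti-PD-1 4 (0.0595) and chemokines without anti-PD-1 1 (0.0592) or 3 (0.0567). Proliferation genes were not called (median -0.13, adjusted p = 0.525), with medians of 0.13 without anti-PD-1 library 1 and -0.21 without Solution library 1, and they were called lower without anti-PD-1 library 4 (-0.43, adjusted p = 0.0284). Fibroblast genes were not called either (-0.47, adjusted p = 0.221, and a median of -0.02 without anti-PD-1 library 1). Naive and memory T cell genes (median -0.25, and 0.00 without anti-PD-1 library 1, while camera pointed up at adjusted p = 0.538) and hypoxia genes (adjusted p = 0.71) were not called. Immediate early genes were not called as a list (-0.37, adjusted p = 0.0862), although Egr2 (-1.68), Ier3 (-1.23), Junb (-0.90) and Egr1 (-0.70) fell, and the list was called without Solution library 1 (0.0373) or 3 (0.0315) or anti-PD-1 library 1 (0.0415).

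**Figure D3:**
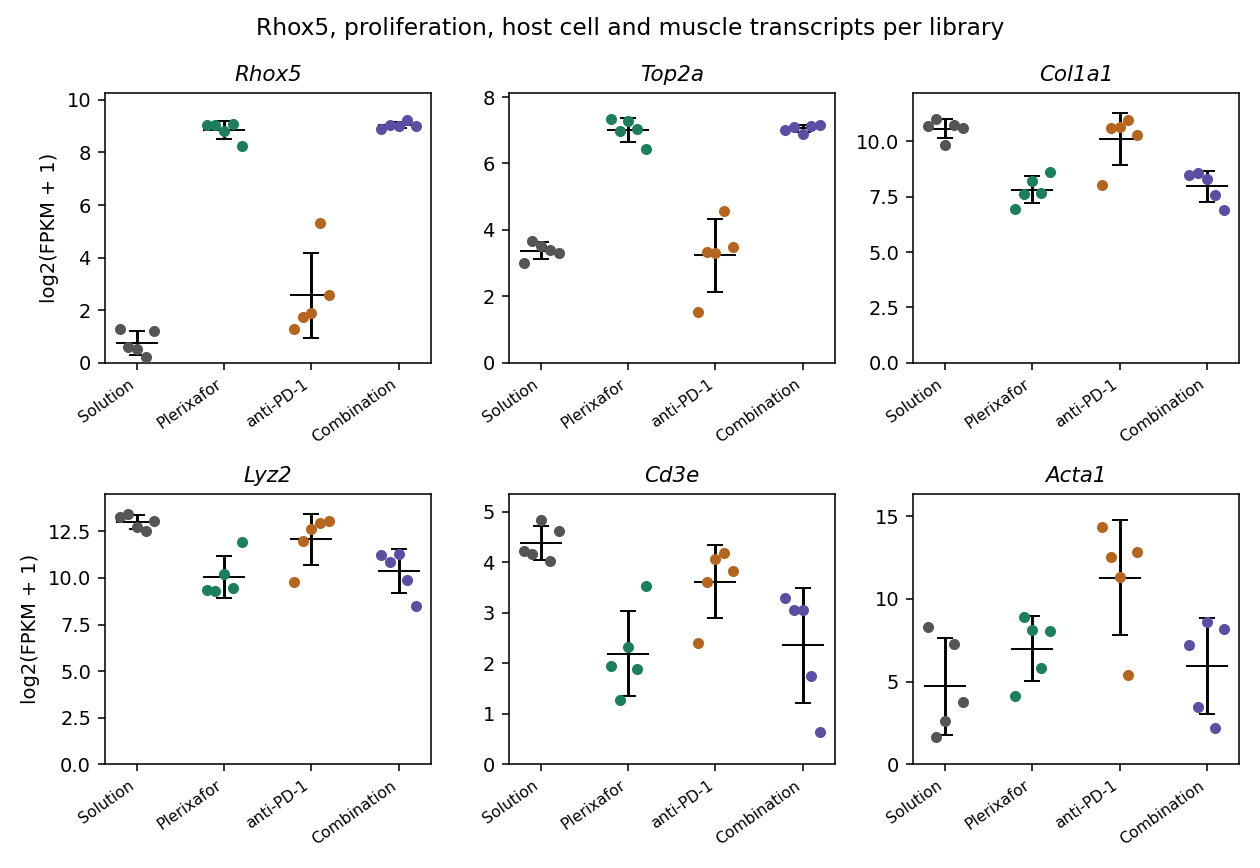
Expression, as log2(FPKM + 1), of Rhox5, Top2a, Col1a1, Lyz2, Cd3e and Acta1 (chosen after their values were seen), with 1 point per library and bars at the mean ± SD of each group of 5. Acta1 reached 20550 FPKM in anti-PD-1 library 1 and 41.05 in library 4, where Rhox5 had 38.87 FPKM.

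Combination against Solution asks what both agents changed together. The changes were nearly those of Plerixafor alone: cycling genes and the Rhox5 set were high, and T cell, myeloid, fibroblast and endothelial genes were low. Muscle genes, high under the antibody alone, were not called (adjusted p = 0.768), and their median of 0.59 ranged from -0.02 without Solution library 2 to 1.35 without Solution library 1.

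By limma 9651 genes passed, 5330 higher and 4321 lower, and 4932 of them differed by more than 2-fold. The median log2 fold change of all genes was 0.10. After median-of-ratios scaling it was -0.01, with 4772 genes called higher and 4925 lower. Rhox5 reached 527 ± 47.8 FPKM (log2 fold change 8.28, SE 0.51, adjusted p = 1.08e-10), followed by Gchfr (6.16), Prl2c2 (6.03), Bmp4 (6.02), Pitx1 (5.93), Dcaf8l (5.59), Prl2c5 (5.51), Tex11 (5.50), Slc2a3 (5.44) and Cox7b2 (5.29). Chil3 fell most (-5.66), then Retnla (-5.18), Ear2 (-5.16), Cd5l (-4.85), Col6a5 (-4.78), Atp6v0d2 (-4.74), Rnase2a (-4.41), Clec3b (-4.32), Lpl (-4.19) and Ptn (-4.15). Cxcr4 had 7.77 ± 3.11 FPKM (log2 fold change -2.43, SE 0.46, adjusted p = 9.74e-05), and Cxcl12 (-2.30), Pdcd1 (-1.90) and Tox (-1.41) fell as well. Jak2 fell to 8.50 ± 1.17 FPKM (log2 fold change -0.62, SE 0.18, adjusted p = 0.00432). Stat3 had 47.1 ± 5.61 FPKM and did not pass (-0.39, SE 0.19, adjusted p = 0.0743), but it passed after TPM (-0.47), median-of-ratios (-0.52) and quantile (-0.60) scaling and with array weights (-0.34).

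Camera called 16 lists, each with an adjusted p = 0.567 with an estimated correlation, the same lists as for Plerixafor except the B and plasma cell list (median -1.34, adjusted p = 0.056), which was called without Solution library 2 (0.0304), 4 (0.0464) or 5 (0.0424) or Combination library 1 (0.0435) or 2 (0.0425). Proliferation genes rose, 24 of 24 on both counts (median 3.12, adjusted p = 2.23e-07), with Aurka at 38.3 ± 5.87 FPKM. All 18 fibroblast genes (-2.56, adjusted p = 4.99e-06), all 16 T cell genes (-1.88, adjusted p = 0.000292) and 17 of 18 macrophage genes (-2.34, adjusted p = 0.000292) fell, with the same counts adjusted over the list alone. In the exhaustion list (-1.41, adjusted p = 0.0223) 12 of 17 genes fell and 3 rose, with 13 and 3 adjusted over the list alone. Eomes was again high at 36.4 ± 4.46 FPKM, while the T cell list ran from 0.58 to 2.80 on the log2 scale across the Combination libraries. Which cells carried the Eomes RNA was not tested. JAK-STAT genes were lower (-0.94, adjusted p = 0.000924, 16 of 25 lower, 15 adjusted over the list alone). Hypoxia and immediate early genes were not called; the hypoxia median of 0.11 ranged from 0.06 without Solution library 3 to 0.21 without Solution library 2, and the immediate early median of 0.07 from -0.05 without Solution library 1 to 0.20 without Solution library 5, while camera pointed down.

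The fold changes of Plerixafor and Combination against the shared Solution libraries were nearly the same across genes, which are not independent replicates. Both comparisons called 5190 genes higher and 4107 lower, where independent lists of these sizes would share 2256 and 1433 and simulated unchanged groups shared 0. Almost no gene can pass in unchanged groups, so this 0 does not show how much overlap shared controls add. With the controls divided between the comparisons the median overlap was 4617.5 and 3441. The correlation was 0.996 (0.976 with divided controls, 0.457 simulated), and the covariance was 1.55 (1.54 with divided controls, 0.027 simulated). Anti-PD-1 shared 477 higher and 260 lower calls with Combination, against 447 and 133 for independent lists and 7.5 and 9 with divided controls, at a covariance of 0.223 (0.214 divided). With Plerixafor it shared 462 and 256, against 450 and 130, and 0 in each direction with divided controls, at a covariance of 0.234 (0.22 divided). The correlations of anti-PD-1 were 0.263 with Combination and 0.279 with Plerixafor (0.251 and 0.255 divided), below the 0.457 of simulated unchanged groups. Both covariances lay above the simulated 0.027. The lower correlations therefore do not show less shared change than shared controls alone would give. Divided controls leave fewer Solution libraries per comparison, so fewer genes can pass. A check without shared libraries set Plerixafor against Solution beside Combination against anti-PD-1, which called 8078 genes in the same direction and 8 in opposite ones (r = 0.842 and Spearman's rho = 0.894 across genes). The matching check for the antibody, anti-PD-1 against Solution beside Combination against Plerixafor, gave r = -0.142 and rho = 0.054. No gene could be called in both, since Combination against Plerixafor called 0.

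Combination against Plerixafor asks what the antibody added to the antagonist. No gene passed, and the mean level of Cxcr4 was nearly the same in both groups. Camera called the interferon response and the immediate early lists lower at its preset correlation, and neither with an estimated correlation (adjusted p = 0.946) or by fry (adjusted p = 0.977).

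By limma 0 genes passed, 60 had an unadjusted limma p under 0.05, and the smallest adjusted p was 0.9999. Limma-voom also called 0 (55 unadjusted), and so did array weights (3010 unadjusted). Among the genes with the smallest p, none of which passed, were Zfp771 (0.30), Mettl18 (0.28), Aven (0.24), Acat3 (0.34) and Mrps6 (0.23) on the higher side and Vmn2r96 (-0.38), Tet2 (-0.28), Zbtb38 (-0.21), Zfp397 (-0.26) and Parp4 (-0.35) on the lower side. The log2 differences were 0.04 (SE 0.46) for Cxcr4, 0.17 (SE 0.51) for Cxcl12, 0.21 (SE 0.43) for Pdcd1, 0.07 (SE 0.19) for Tox, -0.11 (SE 0.18) for Jak2 and -0.12 (SE 0.19) for Stat3.

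Interferon response genes were called lower (median -0.27, adjusted p = 0.0006), with 0 of 24 genes past on either count, and adjusted p = 0.946 with an estimated correlation. The members with the smallest p were Ifit1 (-0.48), Rsad2 (-0.42), Usp18 (-0.42) and Stat2 (-0.36). Immediate early and heat shock genes were also called lower (median -0.09, adjusted p = 0.0176, 0 of 14 past on either count), again with adjusted p = 0.946 with an estimated correlation, with Atf3 at -0.41 and Fos at -0.40. The interferon median was -0.46, -0.10, -0.43 and -0.08 without Plerixafor library 2, 3, 4 or 5, and -0.47, -0.16 and 0.01 without Combination library 1, 4 or 5, and the call was lost without Plerixafor library 3 (adjusted p = 0.26) or 5 (0.184) or Combination library 4 (0.0738) or 5 (0.808). The immediate early median was -0.14 without Plerixafor library 1 or 5, and its call was lost without Plerixafor library 2 (adjusted p = 0.139) or Combination library 4 (0.0738). T cell genes, not called in all libraries (median 0.09, adjusted p = 0.35), were called higher without Plerixafor library 5 (0.37, adjusted p = 7.17e-06) or Combination library 5 (0.45, adjusted p = 1.47e-09). Cytotoxic, NK cell, B and plasma cell, MHC class II, fibroblast and endothelial genes were called higher without the same libraries. Other libraries moved other lists, also downward. Without Plerixafor library 1 camera called skeletal muscle genes lower (-1.33, adjusted p = 0.000472), and proliferation (0.12, adjusted p = 0.00971) and epithelial genes (0.27, adjusted p = 0.0381) higher. The number of lists called, 2, moved with single libraries: it was 5, 5, 1, 8 and 8 without Plerixafor library 1, 2, 3, 4 or 5, and 8, 5, 7, 0 and 13 without Combination library 1, 2, 3, 4 or 5.

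Combination against anti-PD-1 asks what the antagonist added to the antibody. The change resembled that of Plerixafor against Solution, with muscle genes falling in addition: cycling genes and simple keratins rose, and fibroblast, endothelial, adipocyte and T cell genes fell. Cxcr4, Cxcl12 and Tox were lower with both agents than with the antibody alone.

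By limma 9462 genes passed, 5547 higher and 3915 lower, and 4791 of them differed by more than 2-fold. The median log2 fold change of all genes was 0.15, and after median-of-ratios scaling it was -0.07, with 48.2% of 9605 calls higher in place of 58.6%. Rhox5 (6.48), Lgals7 (5.93), Gchfr (5.37), Slc2a3 (5.20), Sqle (5.19), Krt8 (4.96), Pitx1 (4.91), Tex11 (4.91) and Prl2c2 (4.86) rose, as did Hmga1b (4.85), a near copy of Hmga1 whose level is uncertain. Muscle genes made up the largest falls: Pvalb (-5.98), Atp2a1 (-5.94), Myh4 (-5.71), Ckm (-5.70), Tnnt3 (-5.66), Mb (-5.54), Mylpf (-5.54), Actc1 (-5.42), Tnnc2 (-5.39) and Ckmt2 (-5.37). Cxcr4 fell from 35.1 ± 19.4 to 7.77 ± 3.11 FPKM (log2 fold change -1.84, SE 0.46, adjusted p = 0.00137), Cxcl12 had a log2 fold change of -1.61 (SE 0.51, adjusted p = 0.00794) and Tox of -0.62 (SE 0.19, adjusted p = 0.006). Pdcd1 did not pass (-0.84, SE 0.43, adjusted p = 0.0868), but it did without anti-PD-1 library 1 (-1.23, adjusted p = 0.00637), after median-of-ratios scaling (-1.02) and after quantile normalisation (-0.80). Jak2 (-0.04, SE 0.18) and Stat3 (0.06, SE 0.19) did not differ beyond their error.

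Camera called 10 lists, each with an adjusted p = 0.748 with an estimated correlation. Proliferation genes were higher (median 3.26, adjusted p = 1.45e-07, 24 of 24 on both counts). Fibroblast genes (-2.21, adjusted p = 9.99e-06, 18 of 18), endothelial genes (-1.40, adjusted p = 0.000235, 12 of 13), muscle genes (-5.37, adjusted p = 0.000882, 15 of 15), T cell genes (-1.21, adjusted p = 0.00392, 16 of 16), adipocyte genes (-2.43, adjusted p = 0.0108, 6 of 10) and B and plasma cell genes (-1.50, adjusted p = 0.0416, 7 of 7) were lower, with equal counts adjusted over the list alone. Macrophage genes (-1.33, adjusted p = 0.0108) had 11 of 18 lower and 10 adjusted over the list alone, MHC class II genes (-1.20, adjusted p = 0.0416) 7 of 11 and 2, and JAK-STAT genes (-0.48, adjusted p = 0.0416) 9 of 25 on both counts. Without Combination library 5 the medians were -0.79 for T cells, -0.72 for MHC class II and -0.31 for JAK-STAT genes, and 3 calls were lost without single libraries (adjusted p in parentheses): B and plasma cells without anti-PD-1 1 (0.0589), 2 (0.0522) or 4 (0.0595) or Combination 4 (0.0528) or 5 (0.0604), MHC class II without anti-PD-1 3 (0.0538) or 4 (0.0881) or Combination 4 (0.0528) or 5 (0.0809) and JAK-STAT genes without anti-PD-1 3 (0.0538) or 4 (0.113) or Combination 4 (0.0528) or 5 (0.073). The epithelial list was not called (median 0.21, mean 1.32, adjusted p = 0.657), with a median from -0.09 without Combination library 4 to 0.80 without anti-PD-1 library 3, although Krt18 (4.83), Krt8 (4.96), Perp (3.79) and Krt14 (2.99) rose. NK cell genes, also not called, had a median of -0.31, from -0.56 without anti-PD-1 library 1 to -0.11 without Combination library 5, and a mean of 0.04 (adjusted p = 0.467).

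The interaction asks whether the antibody's effect differed with and without the antagonist. No single gene passed. Camera called 13 lists at its preset correlation, and it called 0 of them with an estimated correlation (adjusted p = 0.759), as did fry. In those preset calls immune lists had medians above 0 and the muscle list one below 0.

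By limma 0 genes passed (1957 at an unadjusted limma p under 0.05, smallest adjusted p 0.199), limma-voom called 1, and array weights called 4071. Without anti-PD-1 library 4 the count was 1007, 93 higher and 914 lower, and without library 3 it was 2. The median log2 difference of all genes was 0.11 (0.03 after median-of-ratios scaling). Genes with the smallest p, none past the threshold, included Cdcp3 (1.87), Cdh1 (2.40), Lhx8 (1.31), Prrg2 (0.50) and Trim29 (1.93) on the higher side and Itga7 (-1.48), Npnt (-1.36), Igf2 (-2.66) and Tmem204 (-1.02) on the lower side. The differences were 0.63 (SE 0.64) for Cxcr4, 0.86 (SE 0.72) for Cxcl12, 1.27 (SE 0.61) for Pdcd1, 0.85 (SE 0.26) for Tox, 0.47 (SE 0.25) for Jak2 and 0.32 (SE 0.27) for Stat3.

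Of the 13 lists, each with an adjusted p = 0.759 with an estimated correlation, the muscle list (median -6.68, adjusted p = 1.22e-14) had 0 of 15 genes past over all genes and 15 adjusted over the list alone, and the epithelial list (2.40, adjusted p = 9.87e-07) 0 of 13 and 10. T cell (0.79, adjusted p = 0.0133), NK cell (0.79, adjusted p = 0.0133) and macrophage genes (1.04, adjusted p = 0.0133) lay higher, and endothelial (-0.31, adjusted p = 0.0133) and erythroid genes (-2.02, adjusted p = 0.0133) lower, with 0 members past except 1 NK cell gene adjusted over the list alone. Without anti-PD-1 library 1 the median was 0.50 for T cells and 0.56 for macrophages, and without Combination library 5 it was 1.25 for T cells. The endothelial median was -0.48 and -0.16 without Plerixafor library 4 or 5, -0.19 without anti-PD-1 library 5, and -0.48 and -0.18 without Combination library 1 or 5. Calls were lost without single libraries (adjusted p in parentheses) for T cells without Plerixafor 2 (0.0773) or Combination 1 (0.0843), NK cells without Combination 1 (0.0513), macrophages without Combination 1 (0.0513), endothelium without Plerixafor 5 (0.116) and erythroid cells without anti-PD-1 1 (0.0625). The count of 13 was 6 without Plerixafor library 2, 7 without Plerixafor library 4, 6 without anti-PD-1 library 1, and 4 or 8 without Combination library 1 or 2.

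Because T cell genes fell as a whole, 8 genes were also set against the mean of 5 T cell transcripts (Cd3d, Cd3e, Cd3g, Cd2 and Lck) in each library. They were Pdcd1, Tox, Havcr2, Lag3, Tigit, Cxcr4, Gzmb and Ifng. In bulk tumour RNA other cells can carry these transcripts too, so a ratio is not an amount per T cell. None of the 40 exact permutation tests passed after adjustment. The smallest p, 0.00794, is the smallest that 5 against 5 libraries can give, with an adjusted p of 0.0635. It was reached by Tigit for Plerixafor (a log2 ratio higher by 3.43), Combination (3.28) and Combination against anti-PD-1 (3.20), and by Ifng for Plerixafor (1.14) and Combination (0.91) against Solution. Tigit RNA did not follow the T cell mean across the Plerixafor and Combination libraries, with a log2 slope of -0.07 (SE 0.09). Relative to the T cell transcripts, Cxcr4 under Plerixafor differed by -0.23 (exact permutation p = 0.548, adjusted p = 0.782). Pdcd1 differed by 0.13 (exact permutation p = 0.603, adjusted p = 0.789) and Tox by 0.77 (exact permutation p = 0.0476, adjusted p = 0.159). The added 1 limits the fall of low genes on the log scale, of Tox under Plerixafor above all. A higher ratio of such a gene does not by itself show more of its RNA per T cell. Without anti-PD-1 library 4, 10 of the 40 tests passed in place of 0.

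Cxcr4 and Tox were correlated within one cluster of libraries, and no raw correlation was detected within the other. Since the clusters were separate, no pooled correlation was computed, and 4 coefficients made up the family. Over the 10 Plerixafor and Combination libraries Pearson's r was 0.874 (permutation p = 0.00138, adjusted 0.00276) and Spearman's rho 0.915 (permutation p = 0.00057, adjusted 0.00228). Leaving out the 2 libraries farthest from the median of Cxcr4 gave r = 0.882, and removing the group means gave 0.888. Over the 10 Solution and anti-PD-1 libraries r was 0.375 (permutation p = 0.257, adjusted 0.343) and rho 0.224 (permutation p = 0.537, adjusted 0.537), and r was 0.412 without the 2 farthest libraries. This second value rested on single libraries, -0.41 without anti-PD-1 library 1 and 0.766 without Solution library 3. In the first cluster both genes followed the T cell mean, with log2 slopes of 0.55 (SE 0.07) for Cxcr4 and 0.15 (SE 0.03) for Tox, so the correlation was not separated from T cell content. With the T cell mean regressed out of both genes, a step added after the results were seen, r was 0.164 (permutation p = 0.647). Plain subtraction of that mean gave 0.913 (permutation p = 0.00011), but it assumes slopes of 1 and so leaves the T cell mean in both genes. In the second cluster r turned to -0.938 (permutation p = 0.00043) with the mean regressed out and to -0.76 (permutation p = 0.0221) with it subtracted. These p-values lay outside the adjusted family of 4. Neither value was recomputed without single libraries, on which the raw r of this cluster rested, so no inverse relation is established.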

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

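All tests of an explanation given here were chosen after the result was seen; the interaction was planned. Among 136 groups of 5 values, 14 had 1 library whose gap to the nearest other exceeded 0.71 of the group's range, where chance alone gives this in about 1 group in 20. Anti-PD-1 library 1 accounted for 5 of them, as the lowest of its group. Its T cell list averaged 2.11 on the log2 scale against 3.40 to 3.72 in the other 4 libraries, its macrophage list 4.96 against 7.16 to 7.89, and its MHC class I list 5.27 against 6.88 to 7.46. Its chemokine list was at 2.27 against 4.23 to 4.82 and its fibroblast list at 6.16 against 7.76 to 8.01. Plerixafor library 5 stood apart from its group toward the Solution values, with the endothelial list at 3.72 (others 2.74 to 2.99), Cxcl12 at 5.66 (2.97 to 3.69) and the proliferation list at 5.23 (5.90 to 6.06).

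The remaining libraries each stood out in 1 or 2 values. Solution library 3 had the highest MHC class I list of its group, 7.91 against 7.46 to 7.59, and the lowest Cxcr4, 4.64 against 5.68 to 5.70. Solution library 1 had the lowest chemokine list, 4.30 against 4.81 to 4.97, and the lowest Stat3, 5.76 against 5.99 to 6.06. In anti-PD-1 library 3 the epithelial list was at 3.41 against 0.92 to 1.47 in the other libraries of its group. Combination library 4 had the highest skin keratinocyte list, 0.15 against at most 0.13, a gap near the floor of these genes.

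The interaction term of the fit, by camera at its preset correlation, called 13 gene lists for a difference in the effect of the antibody with and without the antagonist, and chance cannot be excluded for this count, since 37 of 100 splits called as many (highest other 21). The median log2 difference of effects was 0.79 for T cells, 0.73 for T cell exhaustion, 0.80 for cytotoxic effectors, 0.79 for NK cells, 1.04 for macrophages and monocytes, 0.59 for dendritic cells, 0.91 for MHC class II, 0.47 for JAK-STAT signalling, 0.84 for chemokines and 2.40 for epithelium. It was -0.31 for endothelium, -6.68 for skeletal muscle and -2.02 for erythroid cells. Without anti-PD-1 library 1 the medians were 0.50 for T cells, 0.36 for exhaustion, 0.39 for cytotoxic effectors, 0.56 for macrophages, 0.33 for dendritic cells, 0.56 for MHC class II, 0.19 for JAK-STAT signalling and 0.29 for chemokines. Without Combination library 5 they were 1.25 for T cells, 1.43 for MHC class II and -0.18 for endothelium, and endothelium had -0.48 and -0.16 without Plerixafor library 4 or 5, -0.19 without anti-PD-1 library 5 and -0.48 without Combination library 1. Calls were lost without single libraries, with adjusted p in parentheses. T cells were not called without Plerixafor 2 (0.0773) or Combination 1 (0.0843), NK cells without Combination 1 (0.0513), macrophages without Combination 1 (0.0513), endothelium without Plerixafor 5 (0.116) and erythroid cells without anti-PD-1 1 (0.0625). Exhaustion was not called without Solution 2 (0.0634), Plerixafor 1 (0.062), 2 (0.0806) or 4 (0.0753), anti-PD-1 1 (0.0625), 2 (0.0786) or 3 (0.0767) or Combination 1 (0.0903), 2 (0.0708) or 3 (0.0603), and cytotoxic effectors without Plerixafor 2 (0.0806) or 4 (0.0764), anti-PD-1 1 (0.0728) or 2 (0.0559) or Combination 1 (0.0905), 2 (0.0614) or 3 (0.0637). Dendritic cells were not called without Plerixafor 2 (0.0806) or 4 (0.0586), anti-PD-1 1 (0.0625) or 4 (0.0593) or Combination 1 (0.0843) or 2 (0.0589), and MHC class II without Solution 1 (0.0525) or 3 (0.0865), Plerixafor 1 (0.0805), 2 (0.138) or 4 (0.133), anti-PD-1 1 (0.0728), 2 (0.0687), 4 (0.0933) or 5 (0.0571) or Combination 1 (0.144), 2 (0.119) or 3 (0.101). JAK-STAT signalling was not called without Plerixafor 2 (0.0813) or 4 (0.0753), anti-PD-1 1 (0.0641) or Combination 1 (0.0903), and chemokines without Plerixafor 2 (0.0806) or 4 (0.0862), anti-PD-1 1 (0.1) or 3 (0.0547) or Combination 1 (0.0903), 2 (0.0739) or 3 (0.0616). None of these lists was called with an estimated correlation (adjusted p = 0.759) or by fry, and by limma 0 single genes passed, with 1957 at an unadjusted limma p under 0.05, 1 by limma-voom and 4071 with array weights.

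The first pattern weighed is the set of genes high in the Plerixafor and Combination libraries and nearly absent from the others. For depth or normalisation as its source, 93.3% of the calls for Plerixafor against Solution were kept in the same direction after median-of-ratios scaling. This share covers all calls, not this set alone. The scaling moved the median log2 fold change only from 0.129 to -0.005. Differences as large as those of this set would be kept under it in any case, so the share does not test their source. In the same comparison fibroblast and endothelial genes differed by -2.69 (SE 0.33) and -1.01 (SE 0.19) log2 units, -1.67 (SE 0.20) apart. This gap cannot exclude a lower share of the component carrying this set as the whole source of the higher host cell lists in the Solution tumours. Endothelial genes started from a lower level, where the added 1 limits a fall on the log scale, and the component's own level of either list was not measured. A single cell component present in different shares is consistent with anti-PD-1 library 4, where 44 genes of this set stood at a median of 8.26% of their Plerixafor mean with quartiles of 7.40 and 9.14%, a spread of 0.3 log2 units, while they stood at 0.408 to 1.14% in the other anti-PD-1 libraries and at 67.2% in Plerixafor library 5. An exchange of the labels of whole groups cannot be told apart from an effect of the antagonist, because 0 groups had libraries on both sides of the first component. Rhox5 reached 301.7 FPKM or more in every Plerixafor library and at most 1.43 in the Solution libraries, so an effect of the drug on the tumours remains open beside tumours of different make-up, and neither is decided here.

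The second pattern is the muscle RNA in the anti-PD-1 libraries 1, 2, 3 and 5. Muscle transcripts taking reads evenly from all other genes do not account for the lower genes, since 91.3% of the lower calls for anti-PD-1 were kept after median-of-ratios scaling. That scaling rests on genes found in every library, which muscle may express too. It therefore cannot exclude that muscle tissue diluted the other RNA of the piece, and with the muscle level as a covariate 0 genes passed. Skeletal muscle tissue in the tumour piece may be the source of the muscle RNA. The muscle genes differed between libraries 1 and 3 by nearly 1 ratio, with an interquartile range of 0.4 log2 units, and Acta1 reached 20550 and 2567 FPKM in them. An effect of the antibody on muscle growth into the tumour was not tested.

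The third pattern is Tigit, which was higher in the Plerixafor and Combination libraries while T cell genes were lower. A fixed higher amount of Tigit RNA per T cell is excluded as the whole source by its slope on the T cell mean in those 10 libraries, -0.071, which reached only 0.11 at 2 standard errors above. The slopes of Lag3, Gzmb, Ifng, Pdcd1, Cxcr4 and Havcr2 were 0.89, 0.80, 0.77, 0.68, 0.55 and 0.46, and that of Tox was 0.15, at 0.576 FPKM or less, where the log scale is flat. Tigit RNA from a component other than T cells is consistent with that slope, and with Combination library 5, which had 18.5 FPKM of Tigit beside 0.547 of Cd3e. In the Solution and anti-PD-1 libraries the slope of Tigit was 0.98 (SE 0.08).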

How the results depend on the processing

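Limma-voom, the muscle covariate, anti-PD-1 library 4 alone, leaving out 3 libraries and regressing out the T cell mean were chosen after the results were seen; the other alternatives were planned. The named genes gave 17576 values under the alternatives, for 741 pairs of gene and contrast. Of these 16706 kept their side of the threshold, with their direction where they passed, 542 were no longer past it, 296 were newly past it and 32 reversed. A value past the threshold in neither fit counts as kept even where its sign differed. The 9577, 9651 and 9462 genes called for Plerixafor, for Combination and for Combination against anti-PD-1 stayed within 1.5 times under every alternative, and the 0 genes for Combination against Plerixafor stayed at 0.

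For anti-PD-1 against Solution the count of 1454 genes became 899 with a minimum of 5 FPKM, where fewer genes were tested, 2240 after quantile normalisation, 0 in a fit of only these groups, 4163 with array weights, 767 by limma-voom, 49 with library 4 as the only anti-PD-1 library, 0 with the muscle covariate and 3020 without 3 distant libraries (Plerixafor 5, anti-PD-1 1 and 4). For the interaction 0 genes became 4071 with array weights, 1 by limma-voom, 19 with library 4 alone and 1715 without the 3 distant libraries. With library 4 alone, that sample is assumed to vary like the other groups. The cause was not tested for these changes, except that the muscle covariate removes muscle signal by construction. The fit of only the groups compared was not made for the interaction.

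Among gene lists, an estimated correlation in camera called 0 for Plerixafor, 0 for anti-PD-1, 0 for Combination, 0 for Combination against Plerixafor, 0 for Combination against anti-PD-1 and 0 for the interaction, in place of 17, 16, 16, 2, 10 and 13. Limma's fry called 2 for anti-PD-1, 0 for Combination against Plerixafor and 0 for the interaction. Alternatives that kept a list count within 1.5 times of the main one are not listed here, for fry as for the others. A pseudocount of 0.1 gave 6 lists for the interaction. Median-of-ratios scaling gave 4 for Combination against Plerixafor and 6 for Combination against anti-PD-1, and quantile normalisation 4 for Combination against Plerixafor. Library 4 alone gave 5 for anti-PD-1, 17 for Combination against anti-PD-1 and 5 for the interaction. The muscle covariate gave 10 for anti-PD-1 and 5 for Combination against Plerixafor, and leaving out the 3 distant libraries 10 and 8. The cause was not tested.

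Leaving out each library in turn gave 9133 to 9637 genes and 16 to 18 lists for Plerixafor against Solution, 2 to 4112 and 12 to 18 for anti-PD-1, 9223 to 9523 and 16 to 20 for Combination, 0 to 0 and 0 to 13 for Combination against Plerixafor, 8964 to 10191 and 7 to 14 for Combination against anti-PD-1, and 0 to 1007 and 4 to 17 for the interaction. For anti-PD-1 the lowest count came without anti-PD-1 library 5 and the highest without library 4, and library 4 also gave the 1007 genes of the interaction. Counts beyond 1.5 times 1454 also came without anti-PD-1 library 2 (544) or 3 (2427) and without Solution library 2 (779), 3 (789), 4 (779) or 5 (582), and without anti-PD-1 library 3 the interaction called 2. The ratios to T cells passed in 0 to 10 of 40 tests, 10 without anti-PD-1 library 4. The correlation of Cxcr4 with Tox ranged from 0.841 to 0.911 in the Plerixafor and Combination libraries, and from -0.406 (without anti-PD-1 library 1) to 0.766 (without Solution library 3) in the Solution and anti-PD-1 libraries. With the T cell mean subtracted the former rose from 0.874 to 0.913 (permutation p = 0.00011) and the latter reversed from 0.375 to -0.76 (permutation p = 0.0221). The subtraction assumes a slope of 1 on that mean, where Cxcr4 and Tox had 0.55 and 0.15 in the former and 1.01 and 0.71 in the latter. With the mean regressed out, each gene at its own slope, they were 0.164 (permutation p = 0.647) and -0.938 (permutation p = 0.00043), and the cause of the reversal was not tested. The values with the mean subtracted or regressed out were not recomputed without single libraries.

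The reversed log2 fold changes lay in muscle and a few other genes. With library 4 as the only anti-PD-1 library, the one without high muscle RNA, anti-PD-1 against Solution gave 0.10 for Ier3, 0.132 for Junb, -0.167 for Ttn and -0.153 for Neb. Combination against anti-PD-1 then gave 0.117 for Pvalb, 0.071 for Atp2a1, 0.193 for Myh4, 0.429 for Ckm, 0.26 for Tnnt3, 0.307 for Mb, 0.209 for Mylpf, 0.469 for Tnnc2, 0.018 for Ckmt2, 0.163 for Neb, 0.206 for Ttn, 0.347 for Myh2, -0.062 for Fscn1, 0.474 for Cpa3, 0.489 for Tpsb2, 1.929 for Car3 and 0.518 for Pck1. The muscle covariate gave, for anti-PD-1 against Solution, -0.277 for Ckm, -0.394 for Acta1, -0.248 for Tnnc2, -0.362 for Tnnt3, -0.302 for Pvalb, -0.428 for Mylpf and -0.211 for Tnni2. For Combination against anti-PD-1 it gave 0.564 for Ckm, 0.326 for Tnnt3, 0.279 for Mylpf and 0.583 for Tnnc2. No reversed fold change passed the threshold; the covariate removes the muscle signal by construction, and for the rest the cause was not tested.

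With the replicate number as a block, 9461, 1169, 9551, 0, 9341 and 0 genes and 17, 15, 16, 2, 11 and 12 lists were called in the order of the leave-out ranges. Libraries with the same number did not deviate together: of 30 pairs 7 had a correlation over 0.1, with a range of -0.753 to 0.506 and a median of -0.076. In 0 of 20 libraries was the own number the best match in every other group at once. That is rare by chance too, so this 0 adds little. Libraries of the same number share only that number. The planned edgeR and DESeq2 tests on recovered reads were not run, because the deposited values are FPKM. With the spread between these libraries, simulated 1.5-fold changes for Plerixafor against Solution were recovered in 45.8% of cases, so small changes can be missed. Only 200 of 12687 genes were changed in that simulation, against 9577 called in the real comparison. Fewer changed genes make the adjustment stricter, so this share does not carry over to missing calls of the real comparison. The genes changed in that simulation left out those at the lowest levels.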

Other observations

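All tests in this part were chosen after the results were seen. Pathway sets from the authors' annotation column (310 sets of 10 to 297 genes) were tested as the gene lists were. Camera called 22 sets higher and 88 lower for Plerixafor against Solution, 0 of them with an estimated correlation. Genes of ribosome biogenesis rose most coherently, 65 of 69 higher at a median log2 fold change of 1.37 (adjusted p = 3.14e-12, and 0.924 with an estimated correlation). RNA transport (1.08, 126 of 150 genes higher), the spliceosome (0.94, 112 of 127), the ribosome (0.91, 113 of 133), aminoacyl-tRNA biosynthesis (1.25, 35 of 43) and DNA replication (1.52, 30 of 35) were called higher too. Cytokine receptor interaction (-1.22, 127 of 173 genes lower), lysosome (-0.88, 80 of 117) and cell adhesion molecules (-1.52, 82 of 108) were called lower. The Combination tumours gave 23 sets higher and 89 lower against Solution, and 19 and 80 against anti-PD-1.

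Under anti-PD-1, where muscle genes held 2.90 to 23.45% of FPKM in 4 of the 5 libraries, the higher sets included oxidative phosphorylation (median 0.72, 61 of 113 genes higher, adjusted p = 5.9e-15, and 0.787 with an estimated correlation), the citrate cycle (1.03, 23 of 30 higher) and cardiac muscle contraction (0.85, 38 of 64 higher). The lysosome set was called lower at a median of -0.52 with 8 of 117 genes past the threshold (adjusted p = 2.96e-07, and 0.998 with an estimated correlation), and in all 31 sets were called higher and 54 lower. Between Combination and Plerixafor 13 sets were called higher and 1 lower, the ribosome first at a median of only 0.10 with 0 of 133 genes past the threshold (adjusted p = 3.07e-14, and 0.998 with an estimated correlation). The interaction called 40 sets higher and 29 lower. No set of any contrast was called with an estimated correlation.

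Each count of calls was set against 100 splits of the same libraries into groups of the same size, the real one included; for the interaction the labels were exchanged within each cluster. Chance can be excluded for the gene count of Plerixafor against Solution (9577, highest other split 7226, 1 of 100 as large), of Combination against Solution (9651, highest other 5749, 1 of 100) and of Combination against anti-PD-1 (9462, highest other 6930, 1 of 100). For anti-PD-1 against Solution (1454, highest other 2001) 3 of 100 splits were as large, without adjustment over the gene and list counts. Chance is not firmly excluded there, since another split called more genes, 0 passed in a fit of these groups alone and 2 without anti-PD-1 library 5. For Combination against Plerixafor (highest other 0) and the interaction (highest other 1) the real count was 0, so 100 of 100 splits were as large by construction, which says nothing about chance.

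For the list counts the share of splits as large was under 0.05 only for anti-PD-1 against Solution (16, highest other 16, 4 of 100). This holds for the count taken alone, without adjustment over the 12 counts, so chance is not firmly excluded. An estimated correlation called 0 of these lists and fry 2. Chance cannot be excluded for the list counts of Plerixafor (17, highest other 22, 44 of 100), Combination (16, highest other 24, 59 of 100), Combination against Plerixafor (2, highest other 24, 100 of 100), Combination against anti-PD-1 (10, highest other 23, 57 of 100) or the interaction (13, highest other 21, 37 of 100). Where 2 groups differ, other splits still hold part of that difference, so a high share does not show that the list calls arose by chance either. Splits of the Combination and Plerixafor libraries called up to 24 lists, several times the real 2, and they were not repeated with an estimated correlation, which called 0 for the real groups.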
